A study of Mus musculus with 4 samples.

How the data were processed

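The libraries were 10x Chromium 3' V3 libraries, read with fastp and Cell Ranger 3.0.0 on the mouse genome mm10, per the submitters' processing notes. The deposited values are scores, which the authors made by centring and scaling each gene over all cells of the 4 barcode suffixes and capping at 10, as the values themselves show; the steps between counts and scores are not stated. The matrix holds 2000 genes, and how these genes were chosen is not stated either. All cells were kept, and the total UMIs of each cell could be solved from its scores.

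UMI counts were recovered from the scores. For each of the 1896 genes with a recoverable scale, the lowest score stands for 0 UMIs, and scores above it were turned back to log-normalised values scaled to 10000 per cell and then to UMIs. All 8805561 tested values fell within 0.05 of a whole number, and the totals of all cells were whole. The other 104 genes had no recoverable scale and were counted as 1 UMI wherever detected, a lower bound. A further 105562 values (1.18% of those above 0) were capped, so that levels of the genes concerned are lower bounds, while 0 Ly6d values were capped. In simulated counts put through the same steps, 100% of 2820029 values were recovered. Levels in CPM were summed UMIs of a gene over the total UMIs of the cells concerned.

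Cells were clustered on 1999 genes, without Ly6d, with 30 principal components, 20 neighbours and the Leiden method at resolution 1.0, which gave 38 clusters. A cluster took the name of a cell type when at least 3 of that type's fixed markers were at least 2-fold higher in it than in other cells at 50 CPM or more, with 20 CPM added to both sides. That type also had to have more such markers than any other type and no fewer among the 10 leading genes, clusters under a low depth limit needed a marker among those genes, and under 95% of the cells had to come from 1 barcode set. Of the 38 clusters, 23 were named and 15 were left unnamed, and named types end in "like" because only marker RNA was measured. Doublet-like cells were those with at least 3 detected markers of each of 2 or more other cell types, with acinar markers not counted. They made up 1.75% of the cells of set 1, 2.80% of set 2, 54.6% of set 3 and 5.22% of set 4, and were left in except where stated.

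The marker lists, the 43 gene lists, the cell types and the clustering resolutions were fixed before the data were examined. Of the 762 list genes, 344 were in the file, and 33 lists had at least 5 genes. The naming thresholds, the doublet threshold, the comparison of cells with and without Ly6d and all of its rules were chosen after seeing the data. In that comparison, genes were named when their folds were at least 1.5 in the same direction in both sets, with at least 50 CPM in the cells with or without Ly6d and at most 5% of values capped, up to 12 genes each way. Predicted genes, mitochondrial, ribosomal, haemoglobin, immunoglobulin and sex-linked genes and markers of other cell types were left out of that naming. The gastric gene Gkn2 was left out by the rule on capped values. In simulated data, the fold and level rules named 65 of 65 genes with a 2-fold difference in cluster 4 and 63 of 65 in cluster 9. They named 0 of 67 and 0 of 66 genes with a 1.25-fold difference, which lies below the 1.5-fold limit. Of genes without a difference they named 0 of 75 and 0 of 94. The simulated counts used the same mean for all cells of a cluster and set, without the rule on capped values. They do not show how often genes are named where a cluster mixes unlike parts.

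The planned tests between the knockout and control groups were not run, because the cells carry no sample title. The design had counted on normalised expression for each sample, and the values are scores over pooled cells. Between barcode sets, levels are given without a test. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and gene positions came from GENCODE vM21.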

Results

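Single-cell transcriptomes were measured from the pancreas of mice carrying mutant Kras in which caerulein, a peptide that overstimulates acinar cells, had been given to cause chronic pancreatitis. The labels give 4 samples in 2 groups of 2: mutant Kras control mice and mutant Kras mice with a conditional knockout of Ly6d, a membrane-anchored protein of the Ly6 family. The study asks how pancreatic tumours begin and what part Ly6d plays. The deposited matrix holds 2000 genes, and its cell barcodes end in 4 suffixes that match no sample title. The cells therefore form 4 barcode sets of unknown group, values are given for each set, and no comparison between the knockout and control groups was made.

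Barcode set 1 held 12230 cells, set 2 held 7497, set 3 held 19792 and set 4 held 10431. Total UMI counts were 79048371 in set 1, 120435284 in set 2, 80802547 in set 3 and 124822268 in set 4. The median cell had 4401 UMIs in set 1, 12724 in set 2, 2252 in set 3 and 9133 in set 4. Levels are given in CPM, from the summed UMIs of all cells of a type in 1 set over the total UMIs of those cells. Brackets give exact 95% intervals, Clopper-Pearson for shares and Poisson for levels, which cover counting error only and not differences between mice. Those for levels and folds also leave out differences between cells, and are too narrow where few cells hold the UMIs.

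Ductal or metaplastic-like epithelial cells had the widest range of shares among the named cell types. They made up 44.1% of the cells in set 2 (43.0 to 45.2), 22.97% in set 4 (22.2 to 23.8), 4.98% in set 1 (4.60 to 5.38) and 3.79% in set 3 (3.53 to 4.06). Fibroblast-like cells formed 33.3% of set 4, 16.2% of set 2, 7.57% of set 1 and 5.14% of set 3. Macrophage or monocyte-like cells ranged from 7.92% in set 2 to 14.1% in set 4. Acinar-like cells, which make digestive enzymes, were 4.05% of set 3, 1.21% of set 1, 1.12% of set 2 and 0.45% of set 4. Among epithelial-like cells alone, acinar-like cells formed 50.9% in set 3 (48.4 to 53.4), 18.6% in set 1 (15.99 to 21.5), 2.37% in set 2 and 1.84% in set 4. Endothelial-like cells ranged from 1.36% to 5.45%, neutrophil-like cells from 0.57% to 2.73%, and tuft-like cells, the chemosensory epithelium of injured pancreas, from 0.10% in set 3 to 1.68% in set 2.

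**Figure D1:**
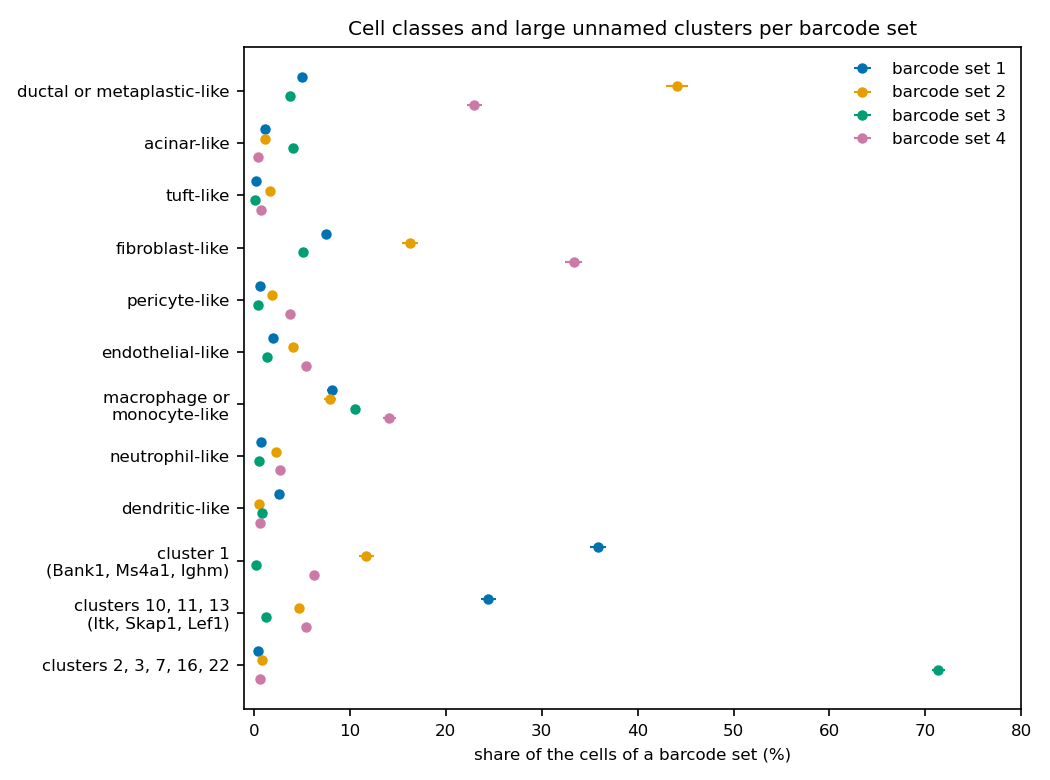
Percent of the cells of each barcode set in the named cell types and in unnamed clusters; points are the 4 sets, and bars are exact 95% binomial intervals. Ductal or metaplastic-like cells run from 3.79% in set 3 to 44.1% in set 2.

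Lymphoid clusters took a large part of set 1. Cluster 1, led by the B cell genes Bank1, Ms4a1 and Ighm, held 35.9% of the cells of set 1, 11.7% of set 2, 6.30% of set 4 and 0.27% of set 3. Clusters 10, 11 and 13, with the T cell genes Trbc2 and Il7r, together held 24.4% of set 1, 5.41% of set 4, 4.74% of set 2 and 1.23% of set 3. These clusters stay unnamed because the file holds only 2 of the fixed markers for B cells and 2 for T cells. In set 3, 71.4% of the cells fell into 5 unnamed clusters in which acinar enzyme genes such as Pnlip and Cela1 stood beside genes of other cell types, against 0.41% in set 1, 0.83% in set 2 and 0.69% in set 4. Without those 5 clusters, macrophage or monocyte-like cells were 36.7% of set 3, fibroblast-like cells 17.96%, acinar-like cells 14.2% and ductal or metaplastic-like cells 13.2%.

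Ly6d was found in 39.7% of ductal or metaplastic-like cells of set 1 (35.8 to 43.7; 242 of 609 cells) and 40.02% of those of set 2 (38.3 to 41.7; 1323 of 3306). In set 3 it was found in 0 of 750 such cells, where a floor of 3 counts allows a share of cells with a UMI of up to 0.40%, and in set 4 in 1.71% (1.23 to 2.31; 41 of 2396). Ly6d levels were 193 CPM in set 1 (185 to 202), 127 CPM in set 2 (124 to 129), 0 in set 3 and 1.92 CPM in set 4 (1.57 to 2.34). As a background measure, fibroblast-like cells held Ly6d in 9.07% of cells of set 1, 3.45% of set 2, 0.10% of set 3 and 0.92% of set 4, at 24.8, 7.98, 0.40 and 2.12 CPM in that order. In set 4 the pooled ductal or metaplastic-like CPM was thus no higher than that background, at median depths of 19199 UMIs in ductal or metaplastic-like and 8674 in fibroblast-like cells. Cluster 9, 1 of the ductal or metaplastic-like clusters, was at 3.41 CPM in set 4 (2.68 to 4.28), with Ly6d in 24 of 1079 cells. The fibroblast-like clusters 5 and 6 of set 4 were at 3.37 CPM (2.36 to 4.66) and 1.48 CPM (1.00 to 2.10). A part of cluster 9 with high Dmbt1 was at 6.54 CPM (4.81 to 8.70), with Ly6d in 9 of 317 cells. With every cell thinned to 2000 UMIs, the shares of ductal or metaplastic-like cells with Ly6d were 16.2% in set 1, 11.8% in set 2, 0% in set 3 and 0.34% in set 4, after leaving out 19, 37, 27 and 60 shallower cells.

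Ly6d, which was left out of the clustering, was common in the B cell gene-led cluster 1 in all 4 sets. In cluster 1, the cluster led by B cell genes, Ly6d was found in 75.6% of cells in set 1, 76.8% in set 2, 79.6% in set 3 and 55.4% in set 4. The levels there were 680 CPM (667 to 693), 650 CPM (623 to 678), 595 CPM (495 to 710) and 423 CPM (392 to 455), in the same order. Plasmacytoid dendritic-like cells of set 1 had the highest level of any named cell type with at least 30 cells in a set, 2223 CPM, and 98.1% of them (101 of 103 cells) held Ly6d. Clusters 10, 11 and 13, with T cell genes, held Ly6d in only 4.32%, 4.08% and 2.40% of cells in set 1. Plasma-like cells of set 1 held Ly6d in 56.1% (37 of 66), and tuft-like cells of set 2 in 14.3% (18 of 126). Ly6d lies on chromosome 15 from 74762056 to 74763620 on the minus strand in 3 annotated exons (mm10, GENCODE vM21). The labels do not say which part was deleted, and the 3' tag counted here can lie outside it, so Ly6d does not check the labels.

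**Figure D2:**
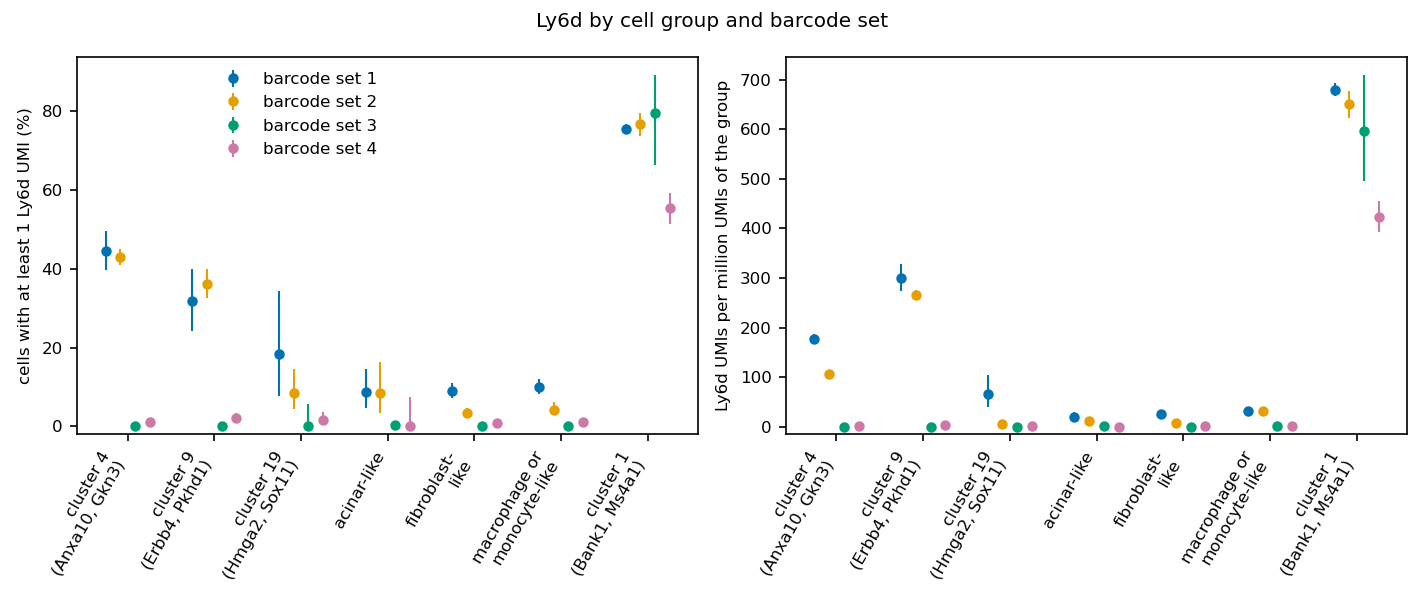
Percent of cells with a Ly6d UMI and Ly6d CPM in ductal or metaplastic-like clusters 4, 9 and 19, in acinar, fibroblast and macrophage or monocyte-like cells and in cluster 1 of each barcode set, with exact 95% intervals. Cluster 1 holds Ly6d in 55.4% to 79.6% of cells, and cluster 4 in 0% in set 3 to 44.6% in set 1.

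Within the ductal or metaplastic-like cells, Ly6d differed in frequency between parts of clusters 4 and 9. In the part of cluster 4 with high Gkn1 and Tff1, secreted products of gastric pit cells, Ly6d was found in 63.7% of cells in set 1 (171 cells), 59.8% in set 2 (969 cells), 0% in set 3 (151 cells) and 0.92% in set 4 (433 cells). In the part with high Muc6, a mucin of gastric gland cells, the shares were 33.0%, 31.2%, 0% and 0.91% over 224, 1168, 156 and 219 cells. The level of Gkn1 in these 2 parts of set 1 was 1152 and 52.7 CPM, and that of Muc6 was 88.8 and 760.0 CPM. A smaller part of cluster 4 was low in both genes, with Gkn1 at 6.90 CPM and Muc6 at 17.4 CPM in set 2. It held Ly6d in 33.7% of 249 cells in set 2, 0% of 51 in set 3 and 1.43% of 279 in set 4. In the part of cluster 9 with high Dmbt1, Ly6d was found in 73.5% of 162 cells in set 2 and 2.84% of 317 cells in set 4. In the largest part of cluster 9 it was found in 28.5% of cells in set 1 and 24.6% in set 2. Cluster 9 as a whole held Ly6d at 300 CPM in set 1 and 266 CPM in set 2, and cluster 4 at 178 and 105 CPM. These parts come from a finer clustering chosen after seeing the data.

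Gkn1 and Tff1, 2 gastric pit genes, were higher in cluster 4 cells with Ly6d than in their neighbours without it. Cells were compared within cluster 4 and within cluster 9 in sets 1 and 2, where at least 30 cells of each kind were present, to ask which genes accompany Ly6d. In cluster 4, 187 cells with Ly6d and 232 without were compared in set 1, and 1029 with 1359 in set 2. Gkn1 was 23.6-fold higher in the cells with Ly6d in set 1 (20.4 to 27.4) and 9.07-fold higher in set 2 (8.61 to 9.56). Tff1 was 17.05-fold and 7.01-fold higher. Of the 17 measured gastric pit and mucin genes, 13 had enough counts, of which Gkn1, Tff1 and Lgals4 were at least 1.5-fold higher in both sets and Muc6 was lower, at 0.54-fold and 0.53-fold. The list as a whole stood at 1.61-fold in set 1 (1.59 to 1.62) and 1.36-fold in set 2 (1.36 to 1.37). Within the Muc6-rich part alone, which holds 1767 of the 4097 cells of the cluster, these list folds were 0.98 and 1.03. Gkn1 stood there at 0.90-fold in set 1 and 1.26-fold in set 2 (1.051 to 1.5005), and Tff1 at 0.97-fold and 1.13-fold (1.08 to 1.18). Folds within the Gkn1-rich part were not measured.

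Other genes at least 1.5-fold higher in both sets of cluster 4 were Prap1 (4.36-fold and 2.98-fold), Phgr1 (4.13-fold and 2.65-fold), Sptssb, the mast cell protease Mcpt2 (2.86-fold and 2.21-fold), Lgals2, Mgst3, Duoxa2, Adam28 and the keratin Krt20 (2.22-fold in each set). Within the Muc6-rich part alone, Adam28 and Krt20 turned lower in set 1. Krt20 was scarce there, at 13.5 CPM (10.1 to 17.6) against 92.9 CPM in the Gkn1-rich part of set 1, so its fold in that part says little. Foxp2, a transcription factor, was lower at 0.66-fold and 0.64-fold. Dclk1, a kinase that marks tuft cells, was the single tuft gene with enough counts and stood at 0.62-fold and 0.60-fold. The ductal identity list stayed near equal, at 0.95-fold and 1.00-fold, with 0 of its 12 sufficiently counted genes past 1.5-fold. Cd74, the invariant chain of MHC class II, was 6.23-fold higher in set 1 and 2.02-fold higher in set 2, and the antigen presentation list stood at 4.61-fold and 1.75-fold. The B cell gene Bank1 was also higher in these cells, at 95.9 against 9.07 CPM in set 1 and 29.5 against 1.63 CPM in set 2. Without cells holding Ms4a1, Bank1 or Ighm, Cd74 stood at 0.87-fold in set 1 and 1.5-fold in set 2.

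In cluster 9, cells with Ly6d had higher levels of Dmbt1, Spink4 and Reg3g, which encode secreted proteins. There were 46 cells with Ly6d and 99 without in set 1, and 248 and 438 in set 2. Dmbt1, a secreted scavenger receptor, was 7.48-fold higher in set 1 (6.70 to 8.37) and 8.79-fold higher in set 2 (8.49 to 9.10). Spink4 was 10.96-fold and 8.56-fold higher, Plac8 6.74-fold and 3.57-fold, and the antimicrobial lectin Reg3g 3.08-fold and 3.01-fold. Ceacam1, Xkr4, Tmc5, Gsta4, Pglyrp1, S100a6, Ctse and Lgals3 were also at least 1.5-fold higher in both sets. Of the 13 ductal identity genes, Krt19, Car2 and Tspan8 were at least 1.5-fold higher in both sets and the chloride channel Cftr was lower, at 0.36-fold and 0.56-fold, while the whole list was lower at 0.81-fold (0.79 to 0.83) and 0.90-fold (0.89 to 0.90). The gastric pit and mucin list stood at 3.29-fold and 3.39-fold, with Ctse and Dmbt1 past 1.5-fold among 7 sufficiently counted genes. Dmbt1 carried much of this fold, with 2828 of the 3632 CPM of the list in cells with Ly6d and 378 of 1103 CPM in cells without it in set 1, and 4054 of 8223 and 461 of 2425 CPM in set 2. Within the largest part of cluster 9 alone, which shares 1507 of its 2234 cells and leaves out the Dmbt1-rich part, the list stood at 1.84-fold in set 1 and 2.33-fold in set 2. These folds mix parts of cluster 9 that differ in both Ly6d and Dmbt1, which was at 5520 CPM in the Dmbt1-rich part and 375 CPM in the largest part of set 2.

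The genes lower in the Ly6d-positive cells of cluster 9 included the growth factor Tgfb2 at 0.18-fold in set 1 (0.12 to 0.25) and 0.50-fold in set 2 (0.45 to 0.57). The prostaglandin synthase Ptgs2 stood at 0.28-fold and 0.51-fold, and Serpine2 at 0.16-fold and 0.54-fold. Within the largest part of cluster 9 alone, Serpine2 was no longer lower in set 2. Spon1, Dscam, Prkg1, Dlc1, Ctnnd2, Nebl, Nkain2, Kcnh8 and Dcdc2a were lower in both sets, from 0.28-fold to 0.56-fold. The EMT list stood at 0.71-fold and 0.66-fold, with 0 of 3 sufficiently counted genes past 1.5-fold in both sets. Ly6a, another Ly6 family gene, was 3.02-fold and 2.13-fold higher, and the EGF receptor ligand Areg 4.54-fold and 1.63-fold. The antigen presentation list stood at 8.55-fold and 1.75-fold, beside Bank1 at 346 CPM against 0 in set 1 and 28.3 against 6.14 CPM in set 2. After leaving out cells with any of 5 B cell genes (Ms4a1, Bank1, Ighm, Igkc and Cd74), 5 cells with Ly6d and 10 without were left in set 1, where Dmbt1 stood at 0.43-fold, Plac8 at 0.60-fold, Reg3g at 0 and the gastric pit and mucin list at 0.52-fold, and no fold could be given for Spink4. In these few cells Lgals3, Pglyrp1, Gsta4, S100a6 and Tmc5 also turned lower, and Spon1, Nebl, Dscam, Kcnh8 and Prkg1 turned higher. Genes were named by size of fold, since cells are not replicates and no test applies, and set 3 with 0 cells with Ly6d and set 4 with 10 in cluster 4 and 24 in cluster 9 were not compared.

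**Figure D3:**
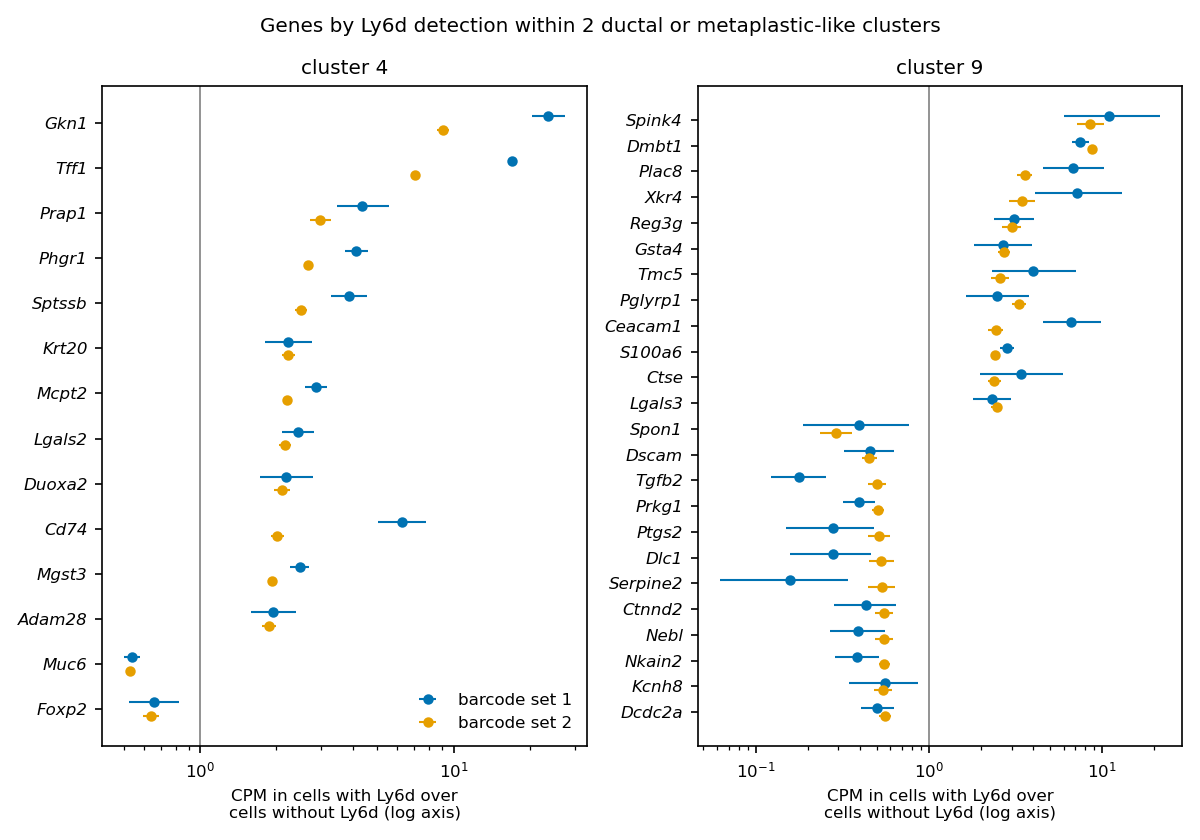
Fold of summed expression in cells with over cells without Ly6d, on a log axis, for the named genes of clusters 4 and 9 in barcode sets 1 and 2; bars are exact 95% counting intervals. In cluster 4, Gkn1 reaches 23.6-fold in set 1 and 9.07-fold in set 2, and Muc6 lies at 0.54-fold and 0.53-fold.

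Across the sets, ductal or metaplastic-like cells kept a near equal ductal identity level, with 12756 CPM over its 13 genes in set 1, 12733 in set 2, 13191 in set 3 and 13115 in set 4. Krt19, Krt7, Krt18, Cldn4, Muc1, Tspan8 and Onecut2 of this list also served as naming markers, so a kept level was partly built in. The gastric pit and mucin list ranged from 15786 CPM in set 4 to 28661 CPM in set 1, but within cluster 4 from 28186 in set 2 to 37833 in set 3. Cluster 4 held 68.8% of these cells in set 1, 72.2% in set 2, 47.9% in set 3 and 38.9% in set 4, where cluster 9 held 45.0%. The EMT list of 11 genes stood at 927 CPM in set 4 (919 to 936), 405 in set 3, 332 in set 2 and 264 in set 1. Within cluster 9 it was near equal, from 684 to 739 CPM, and it was far higher in cluster 19 at 2986, 3720, 2342 and 4494 CPM in sets 1 to 4. Cluster 19 held 15.03% of the ductal or metaplastic-like cells of set 4 and 6.24%, 3.96% and 8.27% of those of sets 1, 2 and 3. Its fibronectin gene Fn1 stood at 2425, 2538, 1961 and 3122 CPM. Only 6 of the 22 genes of the Kras and MAPK output list were measured (Epha4, Ccnd1, Ereg, Areg, Hbegf and Il1rn), so its sum is a narrow measure. Within cluster 4 it ran from 3456 CPM in set 1 to 5334 in set 4, led by Areg at 1550, 1558, 2157 and 3461 CPM in sets 1 to 4.

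Fibroblast-like cells differed between sets in inflammatory genes. The inflammatory fibroblast list of 20 genes stood at 18948 CPM in set 3 (18850 to 19047), 17034 in set 1 (16947 to 17121), 9410 in set 2 (9355 to 9464) and 5257 in set 4 (5232 to 5282). Cxcl1, which draws neutrophils, was 3768 CPM in set 1, 3485 in set 3, 1501 in set 2 and 861 in set 4, and the cytokine gene Il6 was 1926 CPM in set 3, 1189 in set 1, 894 in set 2 and 550 in set 4. The complement gene C3 ranged from 769 CPM in set 4 to 3133 in set 3. The order of the list was the same within cluster 5, from 11149 CPM in set 4 to 24106 in set 3, and within cluster 6, from 2254 CPM in set 4 to 9903 in set 3. The myofibroblast list of 18 genes stood at 3852 CPM in set 1, 6209 in set 2, 5438 in set 3 and 7186 in set 4 over the whole class. Cluster 6 held 54.1% of these cells in set 4 and 24.7%, 36.6% and 26.3% in sets 1, 2 and 3, and within it the myofibroblast list ran from 7032 CPM in set 1 to 10036 in set 3. Igfbp3, a growth factor binding protein of that list, was 488, 912, 1018 and 1661 CPM in cluster 6 of sets 1 to 4. The collagen and matrix list ranged from 26977 CPM in set 4 to 37889 in set 3. Acinar enzyme RNA in these cells, a measure of free RNA, was 5497 CPM in set 3, 1029 in set 1, 510 in set 4 and 367 in set 2.

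**Figure D4:**
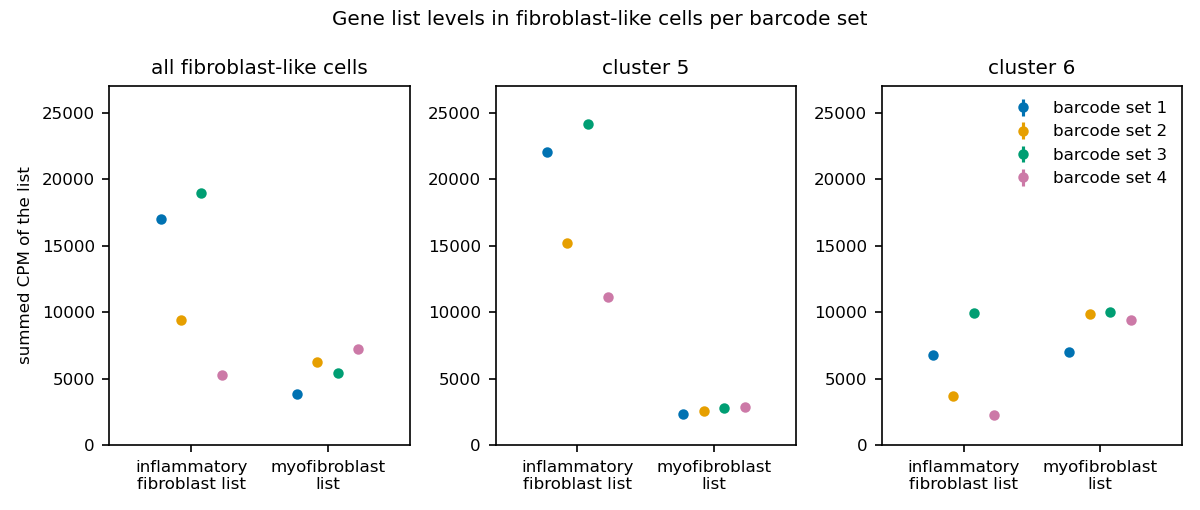
Summed CPM of the inflammatory fibroblast and myofibroblast lists in all fibroblast-like cells and in clusters 5 and 6 of each barcode set, with exact 95% Poisson intervals that are mostly narrower than the points. The inflammatory list runs from 5257 CPM in set 4 to 18948 CPM in set 3 over all fibroblast-like cells.

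Macrophage or monocyte-like cells also differed between sets in inflammatory genes. The NF-kB and inflammatory list stood at 16966 CPM in set 3, 15987 in set 2, 14269 in set 1 and 6930 in set 4. Within cluster 8, which held 62.7% of these cells in set 3 and 60% in set 1, it was 20347, 13437, 7984 and 10164 CPM in sets 3, 1, 2 and 4. Within cluster 12, which held 56.4% in set 4, it was 13073, 12169, 8230 and 7220 CPM in the same order. The acute-phase gene Saa3 made up much of the list in set 2, at 6995 CPM against 721 in set 1, 521 in set 3 and 36.6 in set 4, and cluster 27, led by Saa3 and Prg4, held 30.6% of the macrophage or monocyte-like cells there. The alternative activation list of 17 genes stood at 8390 CPM in set 3, 6820 in set 1, 6031 in set 2 and 3890 in set 4, and within cluster 12 at 1940, 2085, 2314 and 3395 CPM in sets 1 to 4, where the high value of set 4 rests on its member Chil3. Retnla, another member which leads cluster 21, was 5234 CPM in set 3, 3935 in set 2, 3724 in set 1 and 904 in set 4. Cluster 21 held 13.97%, 14.1%, 11.8% and 4.97% of these cells in sets 1 to 4, and within cluster 8 Retnla was 1701, 704, 3240 and 1156 CPM. Chil3, which leads cluster 24 and is second in cluster 12, was 965 CPM in set 4, a lower bound because 124 of its values were capped, and 108, 18.2 and 16.2 CPM in sets 2, 3 and 1. Cluster 24 held 14.5% of these cells in set 4 and 6.23%, 6.74% and 1.51% in those sets, and within cluster 12 Chil3 was 1243 CPM in set 4, with 113 values capped, and 124, 41.6 and 44.5 CPM in sets 2, 3 and 1. The complement gene C1qa ranged from 888 to 1388 CPM.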

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

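The alternatives for cells with and without Ly6d, the clustering alternatives for Ly6d levels, the 1000 UMI minimum and the removal of the 5 unnamed clusters of set 3 were chosen after seeing the data; the other alternatives were planned, though the doublet rule was made stricter after seeing the data. No paired analysis was possible because the barcode sets carry neither a group nor a replicate number. For the same reason the planned group tests and their alternatives (pseudocounts, filters, centring, trend, other count models, other list tests, acinar gene removal and leaving out each library) were not run. A minimum of detected genes was not run either, since the matrix holds 2000 genes.

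Ly6d shares and levels in ductal or metaplastic-like cells moved past their intervals in 1 of 8 cases at resolution 0.5, where the set 2 level was 131 CPM. Cell shares moved more. Macrophage or monocyte-like cells were 7.23% of set 2, 9.74% of set 3 and 13.1% of set 4 at resolution 0.5, and 12.95% of set 4 at resolution 2.0. In set 3 without doublet-like cells, macrophage or monocyte-like cells were 22.7%, fibroblast-like 11.2%, acinar-like 8.68% and ductal or metaplastic-like 8.29%; in set 4 the latter were 94.9% of epithelial-like cells. Without cells under 1000 UMIs, set 3 held 11.4% macrophage or monocyte-like, 4.55% acinar-like and 4.21% ductal or metaplastic-like cells. Without the 5 unnamed clusters those shares were 36.7%, 14.2% and 13.2%, with 17.96% fibroblast-like cells.

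At resolution 2.0 only the largest part of each cluster was compared, so the Gkn1-rich part has no fold. The gastric pit and mucin list was near equal in the Muc6-rich part of cluster 4 and, in cluster 9 of set 1, depended on cells with B cell genes. At resolution 0.5 its folds with over without Ly6d were 1.65 and 1.39 in cluster 4 of sets 1 and 2, and 3.78 in cluster 9 of set 2. At resolution 2.0, in the Muc6-rich part, the largest share of cluster 4, they were 0.982 and 1.03. Gkn1 (0.898), Tff1 (0.971), Krt20 (0.690) and Adam28 (0.724) were no longer higher in set 1 there, with Krt20 at only 13.5 CPM. In set 2 Gkn1 (1.26) and Tff1 (1.13) stayed higher. In the largest part of cluster 9 at that resolution (1507 of 2234 cells, without the Dmbt1-rich part) the list stood at 1.84 and 2.33, and Serpine2 at 1.03 in set 2. With at least 2 Ly6d UMIs the list folds were 1.81 and 1.504 in cluster 4 and 4.60 and 3.78 in cluster 9. Depth matching gave 1.57 and 1.31 in cluster 4 and 2.65 in cluster 9 of set 2. Without doublet-like cells, cluster 4 of set 2 stood at 1.37.

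Removing cells with Ms4a1, Bank1 or Ighm turned Cd74 in cluster 4 of set 1 to 0.873, with the list at 1.57 there and 4.85 in cluster 9 of set 1, where 24 cells with and 87 without Ly6d were left. Removing cells with any of 5 B cell genes (Ms4a1, Bank1, Ighm, Igkc and Cd74) left the list at 1.66 and 1.37 in cluster 4, with 16 and 28 cells in set 1. In cluster 9 of set 1 it left 5 and 10 cells and turned the list to 0.521, with Dmbt1 at 0.426, Plac8 0.605, Lgals3 0.567, Pglyrp1 0.749, Gsta4 0.806, S100a6 0.855, Reg3g and Tmc5 0, Spon1 5.24, Nebl 3.93, Dscam 3.20, Kcnh8 2.33 and Prkg1 2.26. No fold could be given for Spink4 in cluster 9 of set 1, with 0 UMIs left in the cells without Ly6d, nor for Cd74, which that removal itself sets to 0. Named gene folds kept their direction in 76 of 76 cases at resolution 0.5, 71 of 76 at 2.0, 75 of 76 without the 3 B cell genes and 60 of 73 without the 5, and in 76 of 76 with depth matching and with 2 UMIs. Their size was less stable: 37 of 76 moved by over 1.5 times at resolution 2.0, 26 of 73 without the 5 B cell genes, 12 of 76 without the 3, 7 with 2 UMIs, 2 with depth matching and 1 at resolution 0.5. Leaving out doublet-like cells says little about these folds, since it took out 2 of 609 and 18 of 3306 ductal or metaplastic-like cells in sets 1 and 2, and doublets with B or T cells cannot meet its rule with 2 markers each in the file.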

Other observations

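All tests in this part were chosen after the data had been seen; for the removal of cells with B cell genes, the bound was set before its own result was seen. No biological explanation was tested, since the barcode sets carry no group, and a difference between the genotypes of the study stays open as untested.

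Neutrophil-like cells and endothelial-like cells also differed between sets in inflammatory genes. In neutrophil-like cells the NF-kB and inflammatory list stood at 28028 CPM in set 2, 27187 in set 3, 24735 in set 1 and 15664 in set 4, and the chemokine gene Ccl3 at 1496, 1598, 1571 and 538 CPM in that order. In endothelial-like cells the activated endothelial list stood at 3549 CPM in set 1, 3007 in set 2, 2676 in set 3 and 2112 in set 4. Acinar enzyme RNA in endothelial-like cells was 14597 CPM in set 3, 1269 in set 1, 691 in set 4 and 390 in set 2. Cecr2 and the B cell precursor gene Vpreb3 were the first 2 leading genes of clusters 30 and 33, and clusters 25, 30 and 33 held 342 of 349, 230 of 232 and 140 of 140 cells from set 1.

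The 5 unnamed clusters of set 3, with 14125 cells there, held acinar enzyme RNA beside genes of several cell types. Doublets of intact cells are argued against by depth, since the median of 1819 UMIs was 0.239 times that of the named clusters of set 3. However, 75.5% of these cells met the doublet-like rule. That rule is not particular to doublets, since it also took in 71.4% to 75.0% of mesothelial-like cells across the sets. The same ratio of 0.239 is what damaged cells or nearly empty droplets would give, and these may be the source. Free acinar RNA stays open too. Acinar enzyme UMIs per cell were 5.44 times those of fibroblast-like cells of set 3 (221 against 40.7), but acinar genes lead most of these clusters. Other non-acinar cells of set 3 held 57.1 (macrophage or monocyte-like), 60.5 (cluster 1), 99.5 (endothelial-like) and 165 (ductal or metaplastic-like). The last were deeper, at a median of 13760 UMIs, with acinar enzyme RNA at 12185 CPM against 97805 CPM in the 5 clusters.

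Ly6d in ductal or metaplastic-like cells lay apart between sets, at 39.7% of cells in set 1, 40.02% in set 2, 0% in set 3 and 1.71% in set 4. Depth as the cause is argued against, since shares at 2000 UMIs were still 16.2% in set 1 and 11.8% in set 2, against 0.34% in set 4. The full range of 16.2 percentage points is set by set 3, which had 0 Ly6d UMIs to thin. Loss of Ly6d from a whole set is argued against, since its level in cluster 1 differed by 1.61 times between the highest and lowest sets. Free Ly6d RNA as the whole source in sets 1 and 2 is argued against, since the level was at least 7.80 times that in fibroblast-like cells. That ratio does not address B cell RNA or doublets. Leaving out cells with Ms4a1, Bank1 or Ighm kept 122 of 187 cells with Ly6d and 194 of 232 without in cluster 4 of set 1. In cluster 9 of set 1 it kept 24 of 46 and 87 of 99. In set 2 it kept 961 of 1029 and 1327 of 1359 in cluster 4, and 233 of 248 and 426 of 438 in cluster 9. B cell RNA or doublets as a source of part of the Ly6d stay open, most of all in set 1. Ly6d also lay apart in fibroblast-like cells (24.8, 7.98, 0.40 and 2.12 CPM in sets 1 to 4) and macrophage or monocyte-like cells (30.9, 31.2, 0.93 and 2.02 CPM), so the source of the difference stays open, and mislabelled or mixed samples were not tested.

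The gastric pit and mucin list was higher in cluster 4 cells with Ly6d than in those without. Depth is argued against as the whole cause, since the lower of the depth-matched folds was 1.31. Without cells holding any of 5 B cell genes the lower fold was 1.37, in set 2, with 625 cells with and 952 without Ly6d left. The pattern in set 2 thus did not rest on cells holding such a gene. In set 1 only 16 and 28 cells were left. The list holds no B cell gene, so its fold cannot decide whether B cell RNA or doublets gave part of the Ly6d. Within the Muc6-rich part the list folds were 0.982 and 1.03, so a higher frequency of Ly6d in the Gkn1-rich part may account for some of the pattern. That part was set apart partly by pit genes, and folds within the Gkn1-rich part were not measured. It held 109 of the 187 cells with Ly6d in set 1 and 579 of the 1029 in set 2. The list level of cluster 4 cells with Ly6d was 44336 CPM in set 1, above the 43624 CPM of the whole Gkn1-rich part. In set 2 it was 32593 CPM, below the 34070 CPM of that part. The mix of parts may thus not give the whole pattern in set 1, and a link within parts stays open.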
